A study of Homo sapiens with 12 samples.

How the data were processed

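Gene expression was measured in 12 samples of BEAS cells on the Affymetrix HG-U133 Plus 2.0 array: 4 treated with vehicle for 4 h, 4 with RSV for 4 h and 4 with RSV for 24 h. Groups were taken from the sample labels, which number the samples 1 to 4 in each group and do not say whether these were separate cultures or what the number marks. The values as deposited are signal intensity on a linear scale, 1 value per probe set and array. The software that made them is not given in the sources used here. The mean of each array after trimming 2% of the values at each end was 500.1, so the authors' values had been scaled to a common level. The median signal of an array was 93.2 to 123.8, 11.8% to 19.6% of values lay below 16, and 0 values were at or below 0.

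Each value was taken as log2 of the signal plus 16. The deposited scaling was kept because the array medians spanned 0.36 on the log2 scale, under the limit of 0.5. Of 54675 probe sets, 62 controls were left out, and the 60% of the other 54613 with the highest mean over all arrays were tested (32768, with a mean log2 of at least 6.21, a signal of 58). By the platform annotation 41091 probe sets carry 1 symbol, 1801 several and 11721 none. A gene was represented by its brightest tested probe set with 1 symbol, which gave 14408 genes from 27085 probe sets. Gene identifiers were looked up in a RefSeq gene table (41043 probe sets found), and 0 symbols changed. No genome build belongs to the array values, so positions are not given.

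The 3 comparisons were fitted in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend), with all 12 arrays in one model of 3 group means. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested probe sets of a comparison. The errors beside log2 changes are standard errors from the same fit as the p-value beside them, and all tests are two-sided. Gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, with p-values adjusted over the 24 lists of a comparison. The 6 lists written later were adjusted over those 6 alone. A list needed 5 measured genes. Counts adjusted over the list alone apply the Benjamini-Hochberg method to the members of a list. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

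The comparisons, tests, filter, 24 lists, alternatives and rule for named genes were fixed before the data were examined. The rule took, for each comparison, the 10 genes with the largest rise and the 10 with the largest fall among called genes with 1 symbol and no overlap between groups. It added up to 4 members per list by adjusted p, and a preset group of interferon, chemokine, stress and reference genes. 1 preset gene is not reported here. Because the planned fit called few genes, the rule was also applied to the fit with the replicate block (24 h against vehicle) and to the fit without RSV 4 h array 2 (24 h against vehicle and against 4 h), a step taken after the data were seen. Not every gene the rule took is named. A further 6 lists were written after the results were seen and are reported only among the other observations.

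The meaning of the replicate numbers was checked by correlating deviations from group means between arrays. The 12 pairs of arrays with the same number had r of 0.107 to 0.361 (median 0.233), and the 36 other pairs -0.311 to 0.155 (median -0.0916). All 12 arrays correlated best with one of their own number. Every pair was above 0.1, the limit set in advance, so the number was used as a block in an alternative, as planned. The block changed no call of genes between RSV and vehicle at 4 h or between RSV at 24 h and 4 h. The estimated correlation within a number was 0.189.

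The alternatives were quantile normalization, centring each array on its median, added values of 1 and 64, no filter, the upper 40% of probe sets, only the groups compared in the fit, eBayes without trend or robust, array weights and the replicate number as a fixed block or random effect. Others were an unmoderated test per probe set, an adjusted p under 0.01, an added limit of 1.5-fold, the mean of a gene's probe sets, and leaving out each array in turn. For the correlation between comparisons that share vehicle arrays, the arrays were split into pairs and data with no effect were simulated (100 draws), later also with a correlation of 0.189 between arrays of the same number. After seeing the data, fits were added that leave out RSV 4 h array 2 or RSV 24 h array 1 with the block, leave out both, or join the block with the compared groups only, another scaling or the upper 40%.

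The procedure was tested on simulated data with 100 changed probe sets of each size in an RSV 4 h against vehicle comparison. It recovered 40% of 2-fold and 78% of 4-fold changes, and 29% and 70% with the block, with 4 false calls among 32568 unchanged probe sets. A list shifted by 0.5 was called by camera at the preset correlation (adjusted p = 5.82e-14), and 0 of the 23 others. The simulated noise was independent between genes and between arrays. It therefore cannot show how camera behaves when genes of a list are correlated. Nor can it show how the block behaves when arrays of the same number share deviations. Raw image files were not used here, and XIST and genes of the Y chromosome were left out of the named genes.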

Results

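BEAS cells, a name in use for an immortalized line of human bronchial epithelium, were treated with vehicle for 4 h or with RSV (respiratory syncytial virus, an RNA virus of the airways) for 4 h or 24 h. RNA from 12 samples, 4 per group, was measured on an oligonucleotide array with 54675 probe sets. The median signal of an array lay between 93.2 and 123.8 and the highest between 29819 and 42228, and the number of arrays limits the precision of every value. The control group was harvested at 4 h, so virus and time in culture differ together where the RSV 24 h group is compared with vehicle. Against RSV at 4 h, time since exposure and time in culture differ together. The labels do not say whether the 4 samples of a group were separate cultures, so the p-values measure only the spread between these samples.

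RSV 4 h array 2 did not resemble the rest of its group. Along an axis that runs from the vehicle mean (0) to the RSV 24 h mean (1), it lay at 0.856, while the other RSV 4 h arrays lay at 0.274, 0.131 and -0.0732. Its DDIT3, a transcription factor of the stress response, had a log2 signal of 12.88 against a mean of 8.99 in the other 3, and its TXNIP, a regulator of glucose uptake, 9.27 against 12.94. The array was kept in the comparisons planned before the data were examined, and values without it are given where it turns the direction of a named gene or ends a call. RSV 24 h array 1 stood apart as well. It had the lowest mean rank correlation with the other arrays (Spearman's rho 0.902) and the lowest position of its group (0.521). Arrays with the same number in different groups also shared part of their deviations, so most gene values at 24 h against vehicle come from a fit with the replicate number as a block, and the planned fit called 2 genes.

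**Figure D1:**
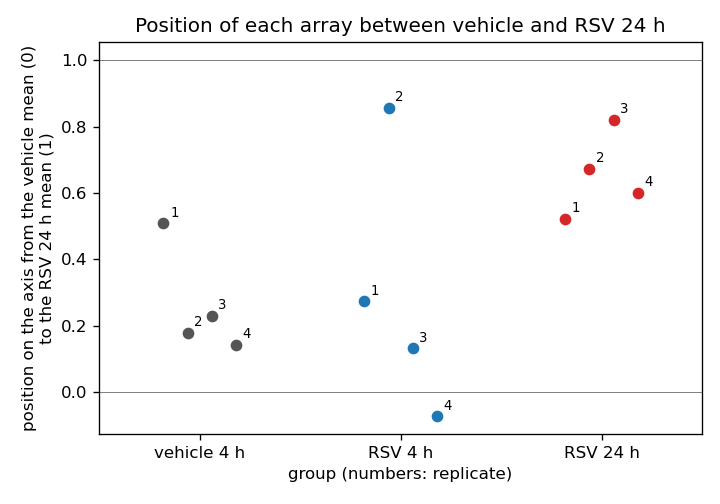
Position of each of the 12 arrays along the axis from the vehicle mean (0) to the RSV 24 h mean (1), by group, with the replicate number beside each point. Vehicle and RSV 24 h arrays were left out of their own axis, which draws them toward the middle; RSV 4 h array 2 lies at 0.856, above the RSV 24 h arrays (0.521 to 0.82), and vehicle array 1 lies at 0.509.

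The comparison of RSV with vehicle at 4 h, matched for time, asks which transcripts differ early after exposure. Antiviral and inflammatory genes gave small or imprecise differences, which do not exclude early changes. IFIT1, an interferon-induced protein that binds viral RNA, differed by 0.68 ± 0.53 (log2 change, SE, n = 4 per group; 0.33 ± 0.53 without RSV 4 h array 2), and ISG15, an interferon-induced ubiquitin-like protein, by -0.15 ± 0.21. CXCL8, a chemokine that attracts neutrophils, differed by 0.15 ± 0.29, which turned to -0.11 ± 0.26 without that array. TNFAIP3, a feedback inhibitor of NF-kB, differed by 0.44 ± 0.40, which turned to -0.12 ± 0.20. DDIT3 differed by 0.89 ± 0.67, and by -0.08 ± 0.25 without the array. No gene passed the test.

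The other preset genes gave log2 differences of 0.11 for MX1, an antiviral GTPase, -0.17 for the chemokine CXCL10, -0.12 for the chemokine CCL5 and 0.13 for the cytokine IL6. Leaving out RSV 4 h array 2 gave 0.05, -0.08, -0.62 and 0.04 for these 4. ICAM1, an adhesion molecule, differed by -0.18, the type III interferon IFNL1 by 0.15 and the stress transcription factor ATF3 by 0.27, which turned to -0.50 without that array. The reference genes ACTB and GAPDH differed by 0.13 and 0.09. IFNB1, the gene of interferon beta, lay under the filter at every time (mean log2 signal 4.60) and was not tested.

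As groups, the 44 measured interferon-stimulated genes had a median log2 change of -0.03 (adjusted p = 0.951), the 18 genes of interferons and viral RNA sensing -0.10 (0.12) and the 25 NF-kB feedback and target genes 0.06 (0.151). Genes of cytosolic ribosomal proteins lay higher in all 22 measured members, with a median of 0.14 (adjusted p = 1.64e-15). Hypoxia and glycolysis genes (0.12, adjusted p = 1.02e-05), oxidative phosphorylation genes (0.06, 8.79e-05) and NRF2 antioxidant genes (0.07, 0.0163) were also called higher. So were the unfolded protein and integrated stress response (0.16), epithelial junctions and keratins (0.10) and cell culture housekeeping genes (0.08), each at 0.0163. None of these 7 lists was called with an estimated correlation (lowest adjusted p = 0.783) or after quantile normalization, where the housekeeping median turned to -0.03. The stress response list stood at -0.03 without RSV 4 h array 2 (adjusted p = 0.791), and the calls of the epithelial (0.775) and housekeeping lists (0.0987) ended.

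The other 14 lists were not called at 4 h. Their medians ran from -0.12 for S phase and DNA replication and -0.10 for leukocyte markers to 0.10 for immediate-early genes. Chemokines and cytokines had a median of 0.02 and a mean of -0.03, and replication-dependent histones a median of 0.03 and a mean of -0.04. Adjusted over the list alone, 1 of 17 measured p53 target genes passed, higher with RSV.

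At 4 h limma called 0 genes higher and 0 lower among 14408 (lowest adjusted p = 0.9999), with 217 genes at an unadjusted p under 0.05. With the replicate block limma called 0, with 355 genes at an unadjusted p under 0.05, and the unmoderated test per probe set also called 0. Both counts at an unadjusted p under 0.05 lie below the share of 0.05 of the 14408 genes that chance alone would give. In 197 genes (1.37%) the values of the groups did not overlap, where chance gives 2.86%.

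The comparison of RSV at 24 h with vehicle at 4 h asks how far the cells had moved from their starting state a day after exposure. The values of this paragraph are from the fit with the replicate number as a block, and of its genes only FUT4 passed in the planned fit. Genes of the stress response were among those that rose most. DDIT3 rose by 3.63 ± 0.60 (log2 change, SE, n = 4 per group; 12.4-fold, adjusted p = 0.0227, and 0.0534 in the planned fit), and PPP1R15A, which restarts protein synthesis after stress, by 2.91 ± 0.47 (7.54-fold, 0.0227, and 0.0534). TNFAIP3 rose 4.39-fold (0.0534 in the planned fit) and CXCL8 2.82-fold (0.0554). TXNIP fell by 3.16 ± 0.52 on the log2 scale (0.0554). FUT4, a fucosyltransferase, fell by 2.46 ± 0.32, and by 2.87 or 1.75 with 1 or 64 added to each signal in place of 16, as its RSV 24 h signals (24.5 to 55.5) were low. IFIT1 rose by 2.48 ± 0.40 (adjusted p = 0.0227, and 0.0726 in the planned fit), whereas ISG15 differed by 0.05 ± 0.17 (0.899).

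In the fit planned before the data were examined, 2 genes passed, both lower: FUT4 (-2.46 ± 0.31, adjusted p = 0.0426) and EIF1AD, a nuclear protein (-1.59 ± 0.21, 0.0426). With limma 0 genes were called higher, while 2486 had an unadjusted p under 0.05, and the unmoderated test per probe set called 2 higher and 4 lower. In 1590 genes (11%) the groups did not overlap, where chance gives 2.86%. Without RSV 24 h array 2, 1 gene was called lower, and 0 without vehicle array 1, 2, 3 or 4, RSV 4 h array 3 or RSV 24 h array 1 or 3. The same fit without RSV 4 h array 2 called 221 genes higher and 466 lower. Leaving out a further array as well gave 87 to 381 higher and 222 to 640 lower, the fewest without vehicle array 2 and the most without RSV 24 h array 1. RSV 4 h array 2 is in neither group compared here. Leaving it out of this fit alone therefore keeps every log2 change and alters only the shared estimate of the spread. A fit of only the compared groups, with all their arrays and no block, called 163 higher and 326 lower.

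With the replicate number as a block, limma called 214 genes higher and 398 lower, and "rose" and "fell" for genes at 24 h against vehicle, with the counts of list members, refer to this fit. Apart from FUT4 and EIF1AD, the genes so named in these paragraphs had adjusted p-values of 0.0534 to 0.304 (LSS) in the planned fit and did not pass there. The p-values of whole lists are those of the planned fit unless the block is named beside them. Of the 214 and 398 genes, 134 and 324 were also called without RSV 4 h array 2 and no block. Both fits compare the same vehicle and RSV 24 h arrays, so a large overlap is built in and is no independent support. The 3.3 and 12.9 shared genes that independent calls would give are therefore not a fair yardstick. The blocked counts rest on several arrays: without vehicle array 2, 3 or 4 or RSV 24 h array 3 or 4 they were 0, with lowest adjusted p-values of 0.0526 to 0.121. Without RSV 4 h array 1 they were 81 and 181, without RSV 4 h array 3 120 and 245, without vehicle array 1 453 and 523, without RSV 24 h array 1 531 and 736, and without RSV 4 h array 2 562 and 954. Lower genes made up 65% of the calls, and 77.4% (122 higher, 418 lower) with each array centred on its median.

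**Figure D2:**
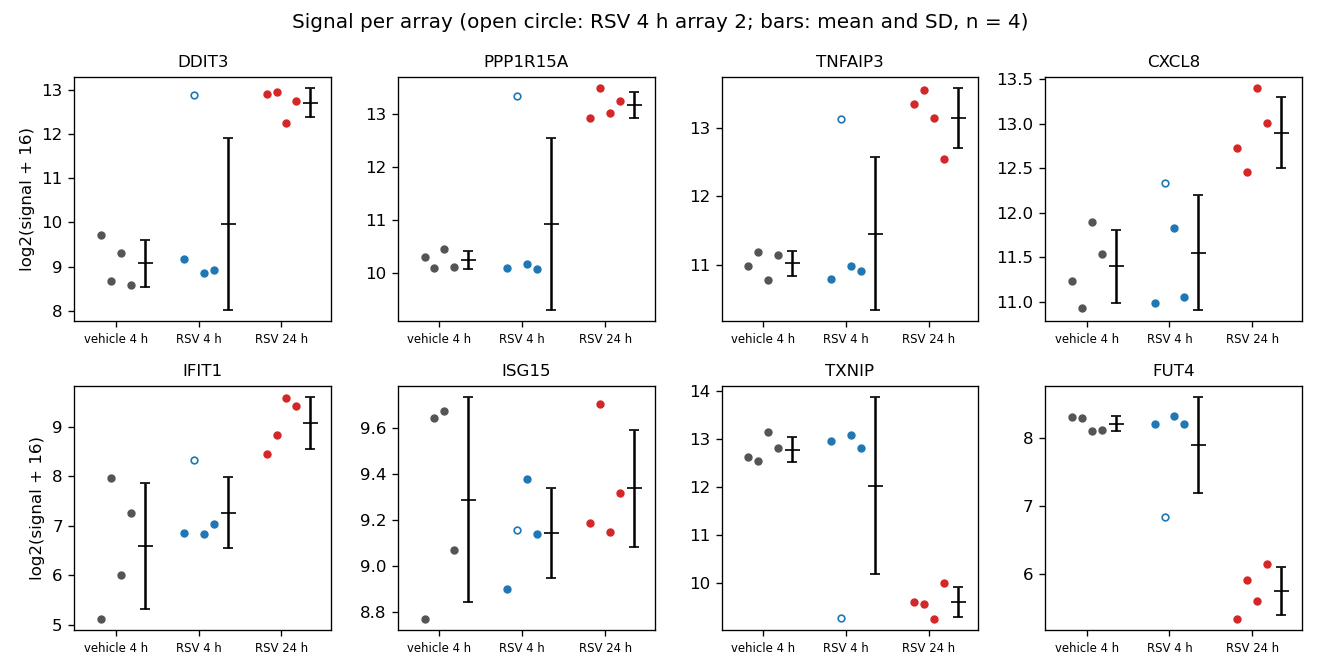
Signal of 8 genes per array, as log2 of signal plus 16, in vehicle 4 h (grey), RSV 4 h (blue) and RSV 24 h (red) arrays, with the mean and SD of each group (n = 4) beside the points and RSV 4 h array 2 as an open circle. DDIT3 stands at 12.71 in the RSV 24 h group and 9.07 in vehicle, ISG15 at 9.34 and 9.29, and RSV 4 h array 2 has 12.88 for DDIT3 and 9.27 for TXNIP.

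The unfolded protein and integrated stress response was called higher as a list by camera, with a median log2 change of 0.51 over 29 measured genes (adjusted p = 5.02e-09, and 0.541 with an estimated correlation). With the block 7 members rose, 0 fell and 22 did not pass, and adjusted over the list alone 15 rose and 1 fell. Beside DDIT3 and PPP1R15A, CHAC1, an enzyme that degrades glutathione, rose by 1.71 ± 0.40 (adjusted p = 0.0408), and ATF4, the transcription factor at the centre of the pathway, by 0.75 ± 0.13. SLC3A2, a subunit of amino acid transporters, rose by 0.95 ± 0.19. ATF3 differed by 2.49 ± 0.65 and missed the threshold (0.0545). RSV 4 h array 2 moved with this group, with 13.34 for PPP1R15A against 10.11 in the other 3 RSV 4 h arrays.

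NF-kB feedback and target genes had a median of 0.32 (adjusted p = 6.55e-05, and 0.492 with an estimated correlation). In the fit with the block 4 of 25 rose, 0 fell and 21 did not pass, and 9 rose and 1 fell adjusted over the list alone. TNFAIP3 rose by 2.13 ± 0.31 and NFKBIA, the inhibitor that holds NF-kB in the cytoplasm, by 1.13 ± 0.16. REL, an NF-kB subunit, rose by 1.49 ± 0.33 (adjusted p = 0.0364) and PTGS2, the inducible cyclooxygenase, by 1.20 ± 0.30 (0.0477), while ICAM1 differed by 0.62 ± 0.29 (0.224). RSV 4 h array 2 held 13.13 for TNFAIP3 against 10.89 in the others of its group.

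Chemokines and cytokines had a median of 0.46 (adjusted p = 0.038, and 0.541 with an estimated correlation), and the call ended without RSV 4 h array 2 (0.0622) and after quantile normalization (0.0628). Of 28 measured genes 2 rose, 1 fell and 25 did not pass, and 8 rose and 3 fell adjusted over the list alone. CXCL8 rose by 1.5 ± 0.25 and CXCL2, also a neutrophil attractant, by 1.04 ± 0.21 (adjusted p = 0.0309), while CSF3, a growth factor of granulocytes, fell. Its RSV 24 h signals (9.2 to 89) lay near the 16 added to every value, which sets the size of its log2 change (-2.61, and -3.33 or -1.71 with 1 or 64 added). CXCL10 differed by 0.59 ± 0.18 (0.0897), CCL5 by 1.06 ± 0.46 (0.197) and IL6 by -0.05 ± 0.47 (0.967).

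Interferon-stimulated genes moved in both directions, with a median of 0.14 that missed the threshold in the planned fit (adjusted p = 0.0533) and passed it with the block (0.0305, and 0.519 with an estimated correlation). Of 44 measured members 3 rose, 2 fell and 39 did not pass, and 8 rose and 4 fell adjusted over the list alone. The risers were IFIT1, IFIT2 (1.34 ± 0.30) and IFIT3 (0.93 ± 0.15), members of the same family of interferon-induced antiviral proteins. ZC3HAV1, which directs viral RNA to decay, fell by 1.46 ± 0.28, with 2 of its 3 probe sets in that direction, and ZNFX1, a helicase that senses RNA, fell by 1.06 ± 0.23. MX1 differed by 0.68 ± 0.27 (adjusted p = 0.169). The vehicle arrays had an SD of 1.27 for IFIT1.

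Genes of interferons and viral RNA sensing had a median of -0.19 (adjusted p = 0.0773). Of 18 measured, 0 rose and 2 fell, and 4 fell adjusted over the list alone. MYD88, an adaptor of toll-like receptors, fell by 0.53 ± 0.12 and TRAF3, a signalling protein upstream of interferon genes, by 0.74 ± 0.16, with 1 of its 2 probe sets in that direction. IFNL1 differed by 0.33 ± 0.26 (0.488). Genes of MHC class I antigen presentation, with a median of 0.13, were called with the block (0.0412, and 0.506 with an estimated correlation) and not in the planned fit (0.0773), and 0 of 18 passed alone.

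Immediate-early genes split, with 4 risers and 3 fallers among 27 and a median of 0.33 (adjusted p = 0.253); 9 rose and 4 fell adjusted over the list alone. KLF4, a transcription factor, rose by 1.96 ± 0.34 and EGR1, a growth-induced transcription factor, by 1.54 ± 0.25. The AP-1 subunits FOS and FOSL1 fell by 1.56 ± 0.27 and 0.84 ± 0.20.

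Cholesterol biosynthesis was called lower as a list by camera, with a median of -0.30 and 0 of 19 members above 0 (adjusted p = 0.000415, and 0.541 with an estimated correlation). LSS, the cyclase that makes lanosterol, fell by 0.60 ± 0.12 (0.0325), the other 18 did not pass, and 7 fell adjusted over the list alone. IDI1 differed by -1.24 ± 0.34 (0.065) and HMGCS1 by -0.81 ± 0.21 (0.0549), both enzymes of the mevalonate pathway. Hypoxia and glycolysis was called higher as a list, with a median of 0.13 (adjusted p = 2.87e-05, and 0.541 with an estimated correlation), with 3 risers and 0 fallers among 26 and 7 risers adjusted over the list alone. ADM, a vasodilator peptide, rose by 2.94 ± 0.52, the glucose transporter SLC2A3 by 1.18 ± 0.25 and hexokinase HK1 by 0.50 ± 0.12.

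The cell cycle lists lay lower. S phase and DNA replication had a median of -0.22 (adjusted p = 0.038, and 0.693 with an estimated correlation) and G2 and mitosis -0.23 (0.0447, and 0.693), with 0 of 33 and 0 of 35 members called. Both calls ended without RSV 4 h array 2 (0.0711 and 0.0879) and after quantile normalization (0.0741 and 0.0844), and the G2 and mitosis median turned to 0.07 without RSV 24 h array 3. CCNB1, a mitotic cyclin, differed by -0.71 ± 0.20 (0.0693). CCNF, a cyclin-like ubiquitin ligase subunit, fell by 1.5 ± 0.19.

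Genes of cytosolic ribosomal proteins lay higher in 22 of 22 members, with a median of 0.18 (adjusted p = 2.26e-08, and 0.631 with an estimated correlation), and 0 members passed alone. After quantile normalization the median was 0.01 and the call ended (0.512).

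Cell death genes were not called as a list (median -0.05, adjusted p = 0.386), but 1 of 25 rose and 3 fell, and 2 rose and 5 fell adjusted over the list alone. PMAIP1, which promotes apoptosis at mitochondria, rose by 1.15 ± 0.24. The death receptor TNFRSF10A fell by 0.75 ± 0.13, its adaptor FADD by 1.00 ± 0.24 and MLKL, the effector of necroptosis, by 0.92 ± 0.19. Among 17 p53 target genes (median 0.02, adjusted p = 0.302) 2 rose and 1 fell, and 4 rose and 2 fell adjusted over the list alone. GADD45A, a stress sensor, rose by 0.78 ± 0.17 and GDF15, a secreted stress cytokine, by 3.36 ± 0.81 (0.0434), against an SD of 1.80 among vehicle arrays, while CDKN1A, a brake on the cell cycle, differed by 0.78 ± 0.20 (0.0556).

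The lists of NRF2 antioxidant genes (median 0.07, adjusted p = 0.0813), heat shock genes (-0.03, 0.607), oxidative phosphorylation (0.06, 0.198) and replication-dependent histones (0.04, 0.607) were not called, with 0 members past the threshold in each. Adjusted over the list alone, 5 NRF2 genes rose and 1 fell. Extracellular matrix and TGF-beta response genes (0.12, 0.35) held 2 risers among 26. Epithelial junctions and keratins had a median of 0.12 and were called with the block (0.0412, and 0.519 with an estimated correlation) but not in the planned fit (0.103), and their median was -0.01 after quantile normalization.

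Markers of other cell types gave 0 genes past the threshold. Fibroblast and endothelial markers had a median of 0.32 (adjusted p = 0.0773 in the planned fit, 0.0102 with the block and 0.506 with the block and an estimated correlation). Airway secretory and ciliated cell markers (0.00, adjusted p = 0.657) and leukocyte markers (0.02, 0.442) were not called. The housekeeping genes had a median of 0.12 (0.302), which turned to -0.04 after quantile normalization, and ACTB and GAPDH differed by 0.18 ± 0.11 and 0.14 ± 0.10.

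Among the other genes with the largest changes, DUSP10, a phosphatase of stress kinases, rose by 3.10 ± 0.53, NFIL3, a transcription factor of the circadian system, by 2.44 ± 0.37, and NUPR1, a stress-induced nuclear protein, by 2.43 ± 0.49. RNASE7, an antimicrobial ribonuclease, rose by 2.39 ± 0.49 and DBP, a circadian transcription factor, by 2.36 ± 0.51. MAT2A, which makes the methyl donor S-adenosylmethionine, fell by 2.66 ± 0.44. CDC42EP2, an effector of CDC42, fell by 2.53 ± 0.43 and the phosphatase PTPRE fell by 2.25 ± 0.32. ARRDC4, a relative of TXNIP, fell by 2.21 ± 0.41. CCDC120 and the probe sets named for the pseudogenes FRMD8P1 and PMS2P2, which may also read related transcripts, fell to signals near or under the filter level of 58 (38.5 to 60.2, 11.6 to 38.7 and 15.5 to 22.9). The value added to each signal sets the size of these changes: -2.06, -2.14 and -2.08 with 16, -2.34, -2.81 and -2.73 with 1, and -1.51, -1.30 and -1.25 with 64.

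Of the 24 lists, 8 were called in the planned fit and 12 with the block, and 0 with an estimated correlation in either (lowest adjusted p = 0.492 and 0.322). In the fit that left out RSV 4 h array 2, 5 were called: the stress response (4.62e-11), NF-kB (2.95e-05), hypoxia and glycolysis (2.46e-05), ribosomal proteins (2.8e-07) and cholesterol biosynthesis (0.00118). With an estimated correlation 0 were called in that fit as well (lowest adjusted p = 0.428). The test fry asks whether the genes of a list move on balance one way, without comparing them with other genes. It called 0 lists in the planned fit (lowest adjusted p = 0.0988) and 0 with the block (0.0513), 2 without RSV 4 h array 2 (0.0221) and 8 with the block and without that array (0.0185). Its form for movement in either direction called 9, 18, 10 and 19 in these 4 fits.

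**Figure D3:**
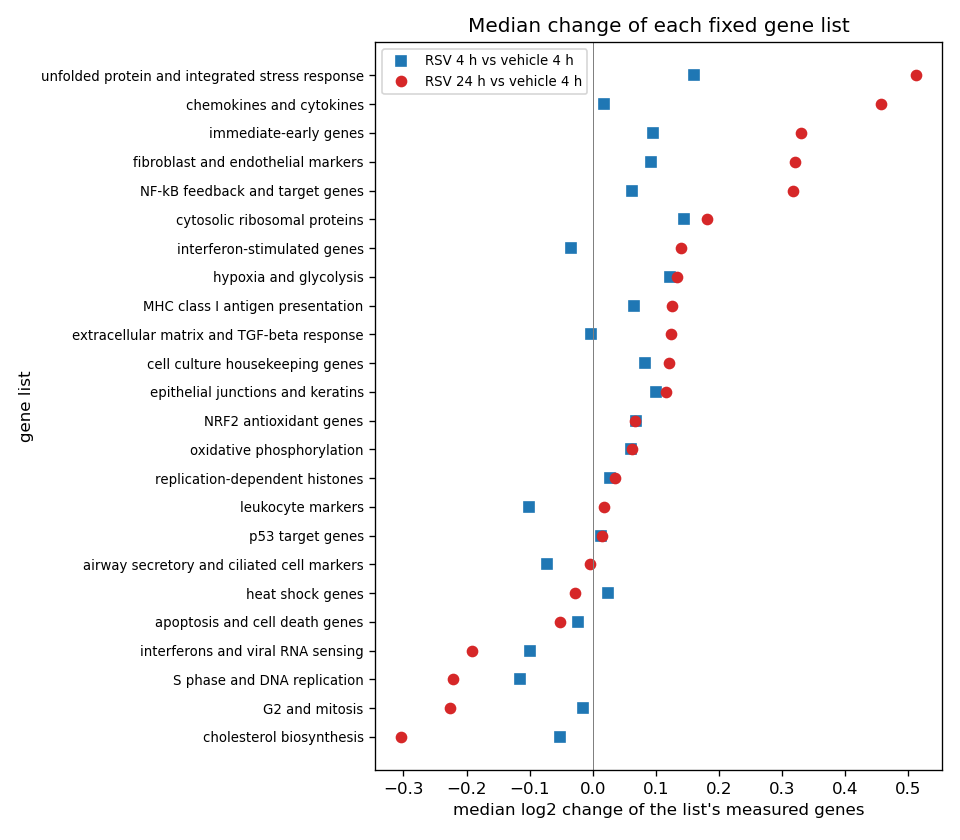
Median log2 change of the measured members of each of the 24 gene lists for RSV 4 h (blue squares) and RSV 24 h (red circles) against vehicle 4 h, ordered by the value at 24 h. The stress response list lies at 0.16 and 0.51, chemokines at 0.02 and 0.46 and cholesterol biosynthesis at -0.05 and -0.30; the ribosomal protein medians are 0.01 at both times after quantile normalization, and the housekeeping medians turn to -0.03 and -0.04.

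The comparison of RSV at 24 h with RSV at 4 h asks how the response moves with time. With all arrays, DDIT3 differed by 2.74 ± 0.67 (n = 4 per group, adjusted p = 0.377) and FUT4 by -2.14 ± 0.31 (0.221), and no gene passed. Without RSV 4 h array 2, a setting to which the rising and falling genes of this comparison refer (n = 4 and 3), DDIT3 rose by 3.72 ± 0.25 (adjusted p = 6.57e-06), PPP1R15A by 3.05 ± 0.15 (4.45e-07) and TNFAIP3 by 2.26 ± 0.20 (6.75e-05). IFIT1 rose by 2.15 ± 0.53 (0.0405), IFIT2 by 1.77 ± 0.32 (0.00951) and CXCL8 by 1.60 ± 0.26 (0.00576). TXNIP fell by 3.33 ± 0.18 (8.21e-07) and FUT4 by 2.49 ± 0.24 (0.000129).

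Other genes with large rises in that setting were NOS1AP, an adaptor of neuronal nitric oxide synthase (2.28 ± 0.37), CHAC1 (2.17 ± 0.43), CAV3, a caveolin of muscle (1.72), PMAIP1 (1.47 ± 0.21) and YPEL2 (1.37). NOS1AP lay lower at RSV 4 h than in vehicle by an uncalled log2 difference of -1.5 ± 0.40 (-1.85 ± 0.37 without that array), and its vehicle array 1 held 8.04 against 6.94 in the others. Large falls included CCDC120 (-2.30), the mitochondrial nuclease EXOG (-1.93), ZNF335, a zinc finger protein (-1.84), POP1, a subunit of RNase P (-1.59), CCNF (-1.62) and SERTAD1, a regulator of cyclin-dependent kinase (-1.42). The non-coding transcripts LINC02833 (1.88), NOP14-AS1 (-1.75) and RBM26-AS1 (-1.73) and the muscle gene NRAP (1.80) passed as well. EXOG, NOP14-AS1 and RBM26-AS1 had RSV 24 h signals of 11.7 to 72.6, so the 16 added to each signal sets the size of their changes.

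As groups in this comparison, the stress response had a median of 0.36 (adjusted p = 1.04e-08, and 0.597 with an estimated correlation) with all arrays and 0.41 without array 2, where 9 of 29 members rose, 0 fell and 15 rose and 1 fell adjusted over the list alone. NF-kB targets had a median of 0.19 (0.000175, and 0.526 with an estimated correlation), and without array 2 4 of 25 rose. Cholesterol biosynthesis had a median of -0.25 (0.000334, and 0.597 with an estimated correlation). These 3 lists were also called without array 2 at the preset correlation (9.77e-12, 0.000269 and 0.00222) and not with an estimated correlation (adjusted p = 0.406, 0.406 and 0.924). Interferon-stimulated genes (0.13), chemokines and cytokines (0.33), hypoxia and glycolysis (0.05) and G2 and mitosis (-0.21) were called with all arrays and lost the call without array 2 (0.28, 0.108, 0.0528 and 0.174). With all arrays and an estimated correlation their adjusted p-values were 0.771, 0.597, 0.909 and 0.909. Without RSV 24 h array 1 the hypoxia and glycolysis median was 0.00, and without RSV 24 h array 3 the G2 and mitosis median turned to 0.05.

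The test fry called 0 lists with all arrays (lowest adjusted p = 0.254) and 2 without array 2 (0.041), and 3 and 10 in its form for either direction. At 4 h against vehicle fry called 0 lists in both forms (0.984).

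With all 12 arrays limma called 0 genes in this comparison, with 1433 at an unadjusted p under 0.05, and 0 with the replicate block, with 2259 at an unadjusted p under 0.05. The unmoderated test per probe set called 0, and 404 genes (2.8%) did not overlap, where chance gives 2.86%. Without RSV 24 h array 4, 1 gene was called lower. Without RSV 4 h array 2 the fit called 177 genes higher and 365 lower, of which 149 and 330 were also called against vehicle in that fit, a comparison that shares the RSV 24 h arrays. The array was left out for its place among the 24 h arrays, a choice these p-values do not account for. Leaving out a further array moved these counts to 65 and 116 (RSV 4 h array 3), 55 and 108 (RSV 4 h array 4), 321 and 543 (RSV 24 h array 1), 94 and 209 (RSV 24 h array 2), 81 and 240 (RSV 24 h array 3) and 105 and 239 (RSV 24 h array 4). Centring each array on its median moved the median change of all genes in this comparison from 0.01 to -0.11.

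Across the 14408 genes, the changes at 4 h and at 24 h against vehicle correlated with r = 0.515, and 70.2% had the same sign, but both used the same vehicle arrays. Simulated data with no effect gave r = 0.5 (0.476 to 0.514) and the same sign in 66.6% from that sharing alone. With a correlation of 0.189 between arrays of the same number as well, r was 0.5 (0.482 to 0.516), a range that holds the observed 0.515. With the vehicle arrays split into pairs, so that each comparison had its own, the mean r was 0.119 (-0.0058 to 0.232 over 6 splits), and -0.096 (-0.232 to -0.0086) without RSV 4 h array 2. Simulated data with no effect, in which arrays of the same number shared part of their spread, gave -0.0716 (-0.0878 to -0.0564) and -0.067 (-0.0833 to -0.0513) for these 2, so 0 is not the value without an effect. Genes are not independent replicates, and no p is given for these values.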

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

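All tests of patterns in this part were chosen after the results were seen, except the tests of scaling and of dim probe sets for the share of lower genes and the comparisons with other splits for the replicate block, for the compared groups only and for the fit without RSV 4 h array 2. Dixon's test marks about 1 in 20 groups of 4 by chance. Of 234 groups of values for the named genes and for measures of whole arrays, 24 held a sample far from the others. All of these were gene values, and 14 of the 24 fell on RSV 4 h array 2. Many of these genes were named for their change at 24 h, so an array at the 24 h end must stand apart for them, and 1 in 20 is not the chance share there.

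RSV 4 h array 2 stood apart for these 14 genes, with the gap as a share of the group's range. Higher than the other 3 were IFIT1 (0.873), TNFAIP3 (0.917), DDIT3 (0.921), ADM (0.95), PPP1R15A (0.968), PMAIP1 (0.856) and REL (0.902). Lower were FUT4 (0.918), EIF1AD (0.86), TXNIP (0.929), MAT2A (0.926), CDC42EP2 (0.911), PTPRE (0.934) and ZC3HAV1 (0.846). Elsewhere, IL6 was low in vehicle array 4 (0.91) and RSV 24 h array 2 (0.931), PMS2P2 low in RSV 4 h array 1 (0.855), and vehicle array 3 high for NFKBIA (0.837) and TRAF3 (0.984). RSV 24 h array 1 was low for PTGS2 (0.858), ATF4 (0.85), LSS (0.917) and HK1 (0.932), and vehicle array 1 high for NOS1AP (0.834).

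The change from vehicle differed between 24 h and 4 h of RSV for 7 lists, tested as the difference itself with camera. Vehicle cancels in this difference, so it is the comparison of RSV 24 h with RSV 4 h given above and no further evidence. The adjusted p was 1.04e-08 for the unfolded protein and integrated stress response, 0.000175 for NF-kB feedback and target genes, 0.000334 for cholesterol biosynthesis, 0.0158 for G2 and mitosis, 0.018 for chemokines and cytokines, 0.0233 for interferon-stimulated genes and 0.0448 for hypoxia and glycolysis. With an estimated correlation these adjusted p-values were 0.526 to 0.909. Without RSV 4 h array 2 the calls of G2 and mitosis (0.174), chemokines and cytokines (0.108), interferon-stimulated genes (0.28) and hypoxia and glycolysis (0.0528) ended.

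RSV 4 h array 2 lay with the RSV 24 h arrays. Poor scaling is argued against, because after quantile normalization it lay at 0.84 (other RSV 4 h arrays up to 0.267, RSV 24 h from 0.547) and centring left it above these too; noise was not tested apart from the pattern itself. A swap with an RSV 24 h array was not settled. The partner in a swap must lie with the RSV 4 h arrays. RSV 24 h array 1, the lowest when held out, lay closer to the other 3 at 54.8% of 819 genes called between these and vehicle. The next lay at 89.5%, and RSV 4 h arrays 1, 3 and 4 at 1.34% to 6.23%. These values speak against a full exchange, but exchanging RSV 24 h array 1 with RSV 4 h array 2 gave 831 called genes against 0. The test with held-out arrays replaced 2 earlier forms, by position (vehicle array 1 at 0.509, RSV 24 h array 1 at 0.521), after their results were seen. At its first bound of 75% the swap stayed open, and the bound was set at the RSV 4 h arrays after its value was seen. A wrong time label may account for it (position 0.856, just above the 24 h range of 0.521 to 0.82), and so may a culture further along in the response, since 98% of 489 genes called between vehicle and RSV 24 h lay closer to the 24 h mean, against 1.23% to 6.75% in the other arrays. These last explanations cannot be told apart, because both put the array near the 24 h end.

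For the changes between vehicle at 4 h and RSV at 24 h, a broad interferon response and time in culture were considered. The design has no vehicle group at 24 h. The interferon-stimulated list had a median of 0.14 (0.05 to 0.18 when leaving out an array). Of 44 members 29 lay above 0 and 9 above 0.5, with an SD of 0.63. A broad response was taken to give a median over 0.5. These values argue against a rise of that size in most listed genes over vehicle at 4 h. A smaller rise, or a response of part of the list, stays open. Clock genes outside those that led the changes had a median of 0.42 over 11 genes, of which BHLHE40 (0.83), CRY1 (-1.31) and CIART (2.28) were called with the block. Time in culture and virus cannot be told apart, because each sample at 24 h had virus.

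More genes were lower than higher at 24 h, 398 against 214 with the replicate block. Scaling as the only cause is argued against for these calls. The lower share was 65% with the deposited scaling, 62.5% after quantile normalization and 77.4% with centred arrays, so its size moved with the scaling. Noise of dim probe sets is argued against, since the share was 64.6% among the upper 40% by brightness. Both may still have changed single calls, and no biological explanation was tested. The share also depends on single arrays. Without RSV 24 h array 1, the array with the highest median signal, it was 58.1% with the block (531 higher, 736 lower). The blocked calls fell to 0 without vehicle array 2, 3 or 4 or RSV 24 h array 3 or 4, which leaves no share there.

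The counts of called genes were compared with other splits of the same arrays. For RSV against vehicle at 4 h and for RSV 24 h against RSV 4 h the real count was 0, which all 35 splits reach, so the comparison says nothing about chance. The highest other split called 104 genes at 4 h and put arrays 1 and 2 of both groups against 3 and 4, which follows the replicate numbers and points to a structure of the samples. With these numbers as a block the real comparison also called 0 genes. For 24 h against 4 h the highest other split called 831 and exchanged RSV 4 h array 2 and RSV 24 h array 1, a structure other than the labels.

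For 24 h against vehicle 1 split of 35, the real one, reached its count of 2 (highest other 0), and the same held for 489 genes from the fit of the compared groups only (highest other 39, again arrays 1 and 2 against 3 and 4). Arrays with the same number resemble each other, so only the splits that part every pair compare like with like. These number 8, too few for a share under 0.05, and the highest other among them was 0 in both fits. With the block there are also 8 splits, too few for a share under 0.05; the real count was 612 and the highest other 0.

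Without RSV 4 h array 2 the real split of 24 h against 4 h called 542 genes, and 1 split of 35, the real one, reached that (highest other 423, with RSV 24 h array 1 among the 4 h arrays). The array had been picked for its place among the 24 h arrays, so this decides nothing about chance. When each of the 35 splits of the 8 arrays also lost the array that gave it most genes, 5 reached 542, the real one included (highest other 1250). The other 4 put RSV 4 h array 2 with the 24 h arrays and lost the 24 h array moved in its place. They thus keep RSV 4 h arrays 1, 3 and 4 apart from 24 h arrays, as the real split does. This comparison therefore neither excludes chance nor measures it.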

How the results depend on the processing

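Settings that leave out RSV 4 h array 2 or RSV 24 h array 1 together with another choice, and the block with only the compared groups, were chosen after seeing the data. The cause was not tested where none is named.

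RSV against vehicle at 4 h kept 0 genes higher and 0 lower in every setting run. For RSV 24 h against vehicle the 0 genes higher became 163 with only the compared groups in the fit, 295 with array weights, 214 with the replicate block, 151 with the block as a random effect and 2 with the unmoderated test. The 2 genes lower became 326, 502, 398, 321 and 4 in these settings. They became 0 after quantile normalization, with no filter, with the upper 40%, with eBayes without trend, at an adjusted p under 0.01 and with the mean of a gene's probe sets. Leaving out an array gave 0 to 221 genes higher and 0 to 466 lower, the highest without RSV 4 h array 2. That array is in neither group compared and acts there only through the shared estimate of the spread.

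With the block, the counts higher and lower were 562 and 954 without RSV 4 h array 2, 531 and 736 without RSV 24 h array 1, and 290 and 524 with only the compared groups. Leaving both arrays out without the block gave 381 and 640. For RSV 24 h against RSV 4 h, leaving out an array gave 0 to 177 higher and 0 to 365 lower, array weights 2 lower, the block without RSV 4 h array 2 366 and 697, and leaving both arrays out 321 and 543.

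The correlation between the changes at 4 h and 24 h, 0.515, was 0.526 after quantile normalization, 0.119 with split vehicle arrays and -0.096 with the split and without RSV 4 h array 2. It was 0.205 without RSV 4 h array 2 and the vehicle arrays whole. Splitting ends the sharing of controls, which lowers r by construction.

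The stress response median at 4 h turned to -0.0322 without RSV 4 h array 2 (range over arrays to 0.268), -0.0741 with the block as well and -0.0322 with both arrays out. After quantile normalization the epithelial list at 4 h stood at 0.0108 with the direction of its test turned downward (adjusted p = 0.905) and the housekeeping list at -0.033. Leaving out an array moved hypoxia and glycolysis for 24 h against 4 h between -0.0025 and 0.162, and G2 and mitosis between -0.392 and 0.072 against vehicle and between -0.376 and 0.0466 against RSV 4 h.

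Of the other values, 6173 log2 changes of named genes and 1109 list medians kept their direction and side of the threshold; 668 and 22 passed it newly, 29 and 86 no longer passed, and 186 and 287 uncalled values moved. Signal over background limits dim genes such as IFNB1, whose signal lay near the 16 added to every value.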

Other observations

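The lists in this part were written after the results of the 24 h comparison were seen, so their tests on the same data are not independent evidence. Their p-values are adjusted over these 6 lists alone and cannot be set beside those of the 24 planned lists. A list of splicing regulators of the SR and LUC7 families, which also holds kinases of SR proteins, moved between vehicle at 4 h and RSV at 24 h. In the fit with the replicate block 10 of 18 measured genes fell, 2 rose and 6 did not pass, with a median log2 change of -0.71 (adjusted p = 8.98e-05, and 0.179 with an estimated correlation). All values of this paragraph and the next are from that fit. SRSF6 fell by 1.32 ± 0.20, LUC7L3 by 1.32 ± 0.25 and TRA2A by 1.18 ± 0.20, factors that select splice sites. The risers were CLK1 (1.16 ± 0.21) and CLK4 (1.19 ± 0.22), kinases that phosphorylate SR proteins and belong to neither family. Ribosome biogenesis factors had a median of -0.36 over 29 genes (8.72e-07, and 0.246 with an estimated correlation), with 5 fallers and 0 risers, among them NIP7 (-1.66 ± 0.23) and UTP3 (-1.64 ± 0.27).

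Circadian clock genes had a median of 0.73 over 14 genes (adjusted p = 0.000399, and 0.182 with an estimated correlation), with 4 risers and 1 faller. CIART, a repressor in the clock, rose by 2.28 ± 0.47 and BHLHE40, a transcription factor of the clock, by 0.83 ± 0.18, beside NFIL3 and DBP, while CRY1, a core repressor, fell by 1.31 ± 0.22. Within the stress response, the ATF4 arm had a median of 0.81 over 16 genes (2.52e-08, and 0.182 with an estimated correlation), with 7 risers and 0 fallers, and the endoplasmic reticulum chaperone arm 0.22 over 13 (0.00977, and 0.426 with an estimated correlation), with 0 genes past the threshold. The difference between the arms was not tested. AP-1 and dual-specificity phosphatase genes had a median of -0.04 over 16 genes (0.637), with 1 riser, DUSP10, and 2 fallers.

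In the planned fit the splicing, clock and ATF4 lists each had an adjusted p of 0.0762 with an estimated correlation. The same fit without RSV 4 h array 2 gave 0.0235, 0.0443 and 0.0235, and 0.219 for ribosome biogenesis. These lists hold genes picked because they led the changes, which lowers these p-values.

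RSV 24 h array 1 had the highest median signal (123.8). Vehicle array 1 and RSV 4 h array 1 had the highest rank correlation of any pair across probe sets (Spearman's rho 0.94). The ratio of 5' to 3' probe sets was -0.02 to 0.05 on the log2 scale for GAPDH and -0.11 to 0.01 for ACTB over the 12 arrays.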
